A study of Mus musculus with 12 samples.

How the data were processed

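Total RNA from spleen cells of wild-type mice was extracted with TRIzol and made into libraries with the VAHTS Universal V6 kit, per the labels' protocols. Neutrophils had been selected with PE-coupled anti-Ly6G and monocytes with PE-coupled anti-CCR2, per the labels' protocols. The 12 libraries fell into 4 groups of 3: neutrophils without therapy and 12 h after CTT, and monocytes 5 days after CTT without and with anti-Ly6G. Groups and replicate numbers were taken from the sample titles.

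The authors deposited whole-number read counts per gene in 1 table for each cell type, with 16805 genes for neutrophils and 16954 for monocytes. Reads had been aligned with HISAT2 to mm10 and counted with HTSeq, per the submitters' processing notes; the versions, the gene annotation and the strand setting are not given in the sources used here. Without a known strand setting, reads of overlapping or antisense genes may have been counted for either gene, and paralogs with near-identical sequence may have lost or exchanged reads, so their values are uncertain. The authors also deposited FPKM values, which equal the count divided by the gene length and by the library's total count, up to a constant. These were used only in alternatives. Every value column matched a sample, so that 0 columns were left out. Entrez gene IDs were matched to a RefSeq table of assembly GRCm38.p6 for coordinates and gene type, with 16709 of 16805 and 16849 of 16954 matched.

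Counts were tested as deposited in R 4.3.3 with edgeR 4.0.16, each cell type on its own. Genes were kept by filterByExpr, which left 13058 in neutrophils and 13294 in monocytes, scaled by TMM, and tested by the quasi-likelihood F test (two-sided) with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of the log2 fold change are approximate, taken as its absolute value divided by the square root of the F statistic of that test. CPM values are TMM-scaled, and means are given with the SD of 3 libraries. The common biological coefficient of variation was 0.275 in neutrophils and 0.114 in monocytes, and the median log2 fold change of all genes was −0.02 and 0.00. With at least 30942849 counts in every library, counting error is small beside the spread between libraries except for genes of a few CPM. No pair of libraries matched within counting error in a chi-square test over genes with at least 10 counts.

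The groups to compare, the tests, 44 gene lists (29 functional groups and 15 sets of cell type markers), the rule for named genes and the alternatives were fixed before the data were examined. Each comparison names the 7 rising and 7 falling genes of largest absolute log2 fold change among protein coding genes past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, leaving out immunoglobulin and T cell receptor genes and symbols that only number a gene model. It also names up to 4 members of each list with the smallest p, the 3 leading genes of a named annotation term, and 11 neutrophil and 12 monocyte genes chosen in advance. A list needed 5 tested genes. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the members of a list only. List tests used camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists. With an estimated correlation, none of the calls on lists held in either comparison. Annotated terms from Gene Ontology and KEGG with 10 to 500 tested genes were tested for genes that rose and genes that fell by a one-sided Fisher's exact test against the annotated tested genes.

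The calling and list steps were tested on simulated data with 200 genes changed by known folds. On 12921 genes drawn from the neutrophil libraries, 0% of genes changed 1.5-fold, 31.3% changed 2-fold and 78.8% changed 4-fold were recovered, and 4 of 77 called genes were unchanged ones. On 13171 genes drawn from the monocyte libraries, the shares were 53.7%, 83.6% and 95.5%, and 9 of 164 called genes were unchanged ones. A list of 20 genes raised 2-fold had a camera adjusted p of 8.38e-36 and 2.86e-70, and 0 of 20 unchanged lists were called in either. All simulated libraries shared the same means apart from the changed genes. None stood apart as control replicate 1 of the neutrophils did, so the recovered shares and false calls may differ in the real comparison. The simulated genes varied independently of each other, so this check does not cover lists whose genes move together. In the data, the estimated correlation was 0.981 for cell cycle genes in neutrophils and 0.944 for B cell markers in monocytes.

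The alternatives were other normalizations (DESeq2 size factors, upper quartile, library totals), no filter or a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited FPKM plus 1 or 0.1 with and without a minimum mean of 1 FPKM, the replicate number as a block, a minimum absolute log2 fold change of 1, all 12 libraries in 1 fit, protein coding genes alone (leaving out 242 and 261 genes), counts without 9 hemoglobin, immunoglobulin and T cell receptor genes, and each library left out in turn. For lists, an estimated correlation and fry were tried. Limma-voom with library quality weights, the quasi-likelihood fit with robust estimation and the overlap without control replicate 1 of the neutrophils were added after the data were seen.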

Results

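Gene expression was measured by RNA-seq in cells selected from the spleens of tumor-bearing mice around a cryo-thermal therapy (CTT), a local tumor treatment that combines freezing and heating. Neutrophils were captured with an antibody against Ly6G, a surface protein of mouse neutrophils, from tumor-bearing mice without therapy (control, n = 3) and from mice 12 h after CTT (n = 3). Monocytes were captured 5 days after CTT with an antibody against CCR2, a chemokine receptor of inflammatory monocytes, from mice that did (n = 3) or did not (n = 3) also receive anti-Ly6G, an antibody used to deplete neutrophils. The 6 neutrophil libraries held 30942849 to 34935547 counted reads each and the 6 monocyte libraries 31865982 to 35956571. Libraries were labelled as biological replicates, with no word on how many mice each one held, so the p-values measure the spread between these libraries. No monocytes from mice without CTT were analysed here, and the monocyte comparison therefore addresses the antibody on top of CTT.

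The selected cells carried transcripts of several spleen cell types. Ly6g stood at 11.8 ± 2.66 CPM (SD, n = 3) in the control neutrophil libraries and 19.2 ± 6.42 CPM after CTT, against 13.6 ± 2.26 CPM in the CTT monocyte libraries and 56.1 ± 7.19 CPM in the anti-Ly6G monocyte libraries. Ccr2 stood at 96.2 ± 22.1 and 169 ± 40.5 CPM in the neutrophil groups (log2 fold change 0.81, SE 0.24, edgeR adjusted p = 0.251) and at 216 ± 41.5 CPM in CTT monocytes. Ly6c2, the Ly6C marker of inflammatory monocytes, stood at 112 and 148 CPM in the neutrophil groups (0.39, SE 0.20, edgeR adjusted p = 0.395). Csf3r, the receptor for the neutrophil growth factor G-CSF, was measured at 485 ± 72.2 CPM in control neutrophils (0.78 after CTT, SE 0.16, edgeR adjusted p = 0.121) and 746 ± 43.4 CPM in CTT monocytes (0.34 with anti-Ly6G, SE 0.17, edgeR adjusted p = 0.209). Csf1r, the receptor for the macrophage growth factor M-CSF, was measured at 733 ± 53.0 CPM in control neutrophils (0.01 after CTT, SE 0.19, edgeR adjusted p = 0.984, with the sign depending on the setting) and 2353 ± 597 CPM in CTT monocytes. Cd74, the invariant chain of MHC class II, stood at 10686 ± 3156 CPM in control neutrophils and 7071 ± 406 CPM in CTT monocytes. Summed over their tested genes, neutrophil markers reached 4802 ± 1031 CPM in control neutrophils and 5426 ± 968 CPM in CTT monocytes, while B cell markers reached 7006 ± 2929 and 5386 ± 1077 CPM. The purity of the selected cells is not given in the sources used here, and "neutrophils" and "monocytes" stand for the cells labelled so. The mean of Ly6g was no higher in the control neutrophil libraries than in the CTT monocyte libraries. B cell markers summed to more than neutrophil markers in control replicates 2 and 3 (8200 and 9150 against 5975 and 4397 CPM) but not in control replicate 1 (3668 against 4036 CPM). In the CTT neutrophil libraries the ranges overlapped, at 7594 to 8071 CPM for B cell markers and 7517 to 12384 CPM for neutrophil markers. These levels come from separately normalized tables of the 2 cell types and were not tested against each other.

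**Figure D1:**
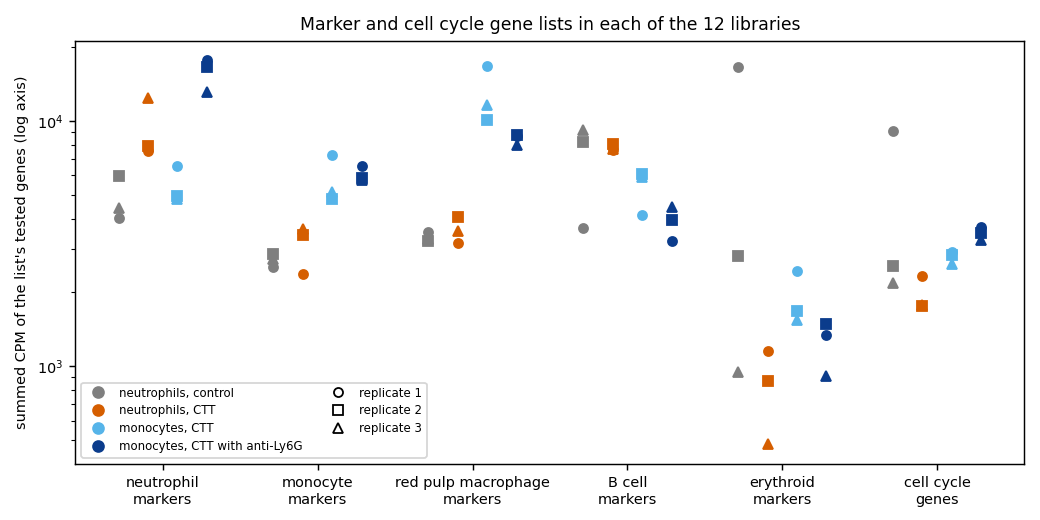
Summed CPM (log axis) of 5 cell type marker lists and of the cell cycle list in each of the 12 libraries, colored by cell type and group, with the replicate number as the marker shape; the cell types come from separately normalized tables. Control replicate 1 of the neutrophils sits at 16583 CPM for erythroid markers and 9116 CPM for cell cycle genes, above every other library.

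Control replicate 1 of the neutrophils stood apart from the other 5 neutrophil libraries. Its erythroid markers summed to 16583 CPM, against 2824 and 950 CPM in the other control libraries and 480 to 1149 CPM after CTT. Its cell cycle genes summed to 9116 CPM (2561 and 2174 CPM in the other controls) and its B cell markers to 3668 CPM (8200 and 9150 CPM). Across genes, its log2 CPM correlated with those of the other neutrophil libraries at a Pearson r of 0.916 to 0.958, while the other 5 correlated with each other at 0.972 or above. Every pair of libraries differed by more than counting error, with a chi-square per degree of freedom of 13.1 or more.

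In the Ly6G-selected cells labelled neutrophils, taken 12 h after CTT, some genes of inflammation and of the sensing of microbes rose. Thbs1, which encodes the matrix glycoprotein thrombospondin-1, went from 132 ± 22.98 CPM (SD, n = 3) in control mice to 815 ± 191 CPM (n = 3), a log2 fold change of 2.63 (SE 0.22). Il1r2, the decoy receptor that captures interleukin-1, rose by a log2 fold change of 2.60 (SE 0.17), and Acod1, the enzyme that makes itaconate, by 2.55 (SE 0.26). Rhov, an atypical small GTPase, rose by 3.18 (SE 0.27), Fosl1, an AP-1 transcription factor subunit, by 3.01 (SE 0.45), the acute phase gene Saa3 by 2.84 (SE 0.33) and the orphan nuclear receptor gene Nr4a2 by 2.12 (SE 0.27). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p-values of these genes lay between 0.0127 (Il1r2) and 0.0467 (Fosl1), and each was higher in all 3 CTT libraries than in any control library.

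All 7 are annotated as protein coding on GRCm38 (mm10). Thbs1 (Entrez gene 21825) lies on chromosome 2 from 118111876 to 118127133 and Rhov (228543) on the same chromosome from 119269201 to 119278008. Il1r2 (16178) lies on chromosome 1 from 40084692 to 40125230, Saa3 (20210) on chromosome 7 from 46711998 to 46719615 and Acod1 (16365) on chromosome 14 from 103047012 to 103056573. Fosl1 (14283) lies on chromosome 19 from 5447698 to 5455938 and Nr4a2 (18227) on chromosome 2 from 57106830 to 57124003.

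Of 17 mature neutrophil receptor genes, 5 rose and 12 did not pass the test, with 14 that rose when adjusted over the list alone. Il1r2 was joined by Trem1, a receptor that amplifies inflammatory signals (log2 fold change 1.86, SE 0.17), and by Clec4d (1.82, SE 0.17) and Clec4e (2.00, SE 0.26), lectin receptors for microbial glycolipids. The list's median log2 fold change was 0.86, with a camera adjusted p = 6.46e-17, and adjusted p = 0.273 with an estimated correlation. Without control replicate 1, 12 of the 17 rose and the median was 0.87. Few neutrophil markers and granule genes passed the test over all genes. Of 16 neutrophil markers 2 rose, the collagenase gene Mmp8 (1.94, SE 0.16) and Retnlg, which encodes a resistin-like protein (1.69, SE 0.25), and 11 rose when adjusted over the list alone. The list's median was 1.07 (camera adjusted p = 1.74e-12, adjusted p = 0.443 with an estimated correlation, 5 rose without control replicate 1). Of 17 genes of the secondary and tertiary granule list 1 rose, with 6 adjusted over the list alone. The list had a median of 0.71 (camera adjusted p = 1.09e-07, adjusted p = 0.477 with an estimated correlation, 2 rose without control replicate 1). None of the 9 primary granule genes rose or fell in the edgeR test (0 of 9, with 6 rising adjusted over the list alone, median 0.93, camera adjusted p = 5.68e-05, adjusted p = 0.477 with an estimated correlation), and Mpo, myeloperoxidase, had a log2 fold change of 0.93 (SE 0.24, edgeR adjusted p = 0.195). The summed neutrophil markers stood at 4802 ± 1031 CPM in control and 9266 ± 2707 CPM in CTT libraries.

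Cytokine and pattern recognition genes rose in part. Of 26 inflammatory cytokine and chemokine genes 3 rose and 23 did not pass, with 12 that rose adjusted over the list alone: the neutrophil attractants Cxcl2 (log2 fold change 1.91, SE 0.14, 295 ± 33.7 to 1106 ± 87.2 CPM) and Cxcl3 (3.40, SE 0.43, from 0.895 ± 0.538 to 9.52 ± 1.54 CPM) and Osm, the interleukin-6 family cytokine oncostatin M (0.98, SE 0.12). For this list the median was 0.78, with a camera adjusted p = 3.39e-09, adjusted p = 0.477 with an estimated correlation, and 5 rose without control replicate 1. Of 25 toll-like and pattern recognition receptor genes 4 rose, among them Cd14, the coreceptor for lipopolysaccharide (1.72, SE 0.15), Tlr13, a sensor of bacterial ribosomal RNA (1.01, SE 0.11), and Nlrp3, an inflammasome sensor (1.84, SE 0.26), with 10 that rose and 1 that fell adjusted over the list alone. The median over the list was 0.33 (camera adjusted p = 1.89e-07, adjusted p = 0.463 with an estimated correlation, 8 rose without control replicate 1). C5ar1, the receptor for complement C5a, rose by 1.37 (SE 0.14). Among all annotated terms tested, 15 of the 267 genes of the Gene Ontology term inflammatory response rose (Fisher's exact test, adjusted p = 1.22e-07, led by Cxcl2, Thbs1 and Cd14), as did 7 of 130 in the cellular response to lipopolysaccharide (adjusted p = 0.0175, led by Cxcl2, Cd14 and Acod1). Other terms passed too, among them external side of plasma membrane (Fisher's exact test, adjusted p = 0.0175). Lung alveolus development and mesoderm development also passed (Fisher's exact test, adjusted p = 0.0441 each). This test treats genes as independent and rests on the 74 genes called in edgeR with all 6 libraries. Those calls were lost when any library other than control replicate 1 was left out.

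Genes linked to myeloid suppression, the acute phase and immediate early responses also rose in part. Of 22 suppressive myeloid genes 3 rose, Lilrb4a, an inhibitory receptor (log2 fold change 1.61, SE 0.18), Socs3, an inhibitor of cytokine signaling (1.02, SE 0.14), and Vegfa, the angiogenic growth factor (1.87, SE 0.26), with 16 adjusted over the list alone. Over the list the median was 1.07 (camera adjusted p = 7.21e-14, adjusted p = 0.273 with an estimated correlation, 6 rose without control replicate 1). Reads of Lilrb4a may be shared with its near copy Lilr4b, so its value is uncertain. Of 17 acute phase and STAT3 target genes 3 rose, Saa3, Socs3 and Lrg1, a secreted leucine-rich glycoprotein (1.49, SE 0.15), with 12 adjusted over the list alone. The group had a median of 0.61 (camera adjusted p = 1.52e-10, adjusted p = 0.294 with an estimated correlation, 5 rose without control replicate 1). Of 20 immediate early genes 2 rose, Nr4a2 and Dusp1, a phosphatase that switches off MAP kinases (0.97, SE 0.14), with 15 adjusted over the list alone. The group's median was 0.80 (camera adjusted p = 3.95e-12, adjusted p = 0.477 with an estimated correlation, 6 rose without control replicate 1). Of 15 heat shock genes 1 rose, the chaperone partner Bag3 (1.29, SE 0.16), with 7 adjusted over the list alone, and 5 rose without control replicate 1, where the median was 0.45. The list's median was 0.25 (camera adjusted p = 9.31e-05, adjusted p = 0.477 with an estimated correlation).

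Erythroid markers and cell cycle genes were the lists whose medians moved most when control replicate 1 was left out. None of 16 erythroid markers fell in the edgeR test over all genes (0 of 16), and 14 fell when adjusted over the list alone. Their median log2 fold change was −2.98 with all libraries and −1.07 without control replicate 1 (camera adjusted p = 1.53e-06 and 2.12e-05, adjusted p = 0.506 with an estimated correlation and all libraries). Hba-a1, an alpha globin gene that may share reads with Hba-a2, read 2103, 375 and 112 CPM in the 3 control libraries and 62.7 to 102 CPM after CTT. None of 30 cell cycle genes passed the test (0 of 30, also adjusted over the list alone), with a median of −1.26, or −0.30 without control replicate 1 (camera adjusted p = 3.61e-08 and 2.29e-07, adjusted p = 0.534 with an estimated correlation). Rrm2, a subunit of the enzyme that makes DNA precursors, read 603 CPM in control replicate 1 and had a log2 fold change of −2.20 (SE 0.79, edgeR adjusted p = 0.334). For 30 oxidative phosphorylation genes the median was −0.44, and −0.14 without that library (0 fell, camera adjusted p = 2.78e-07 and 0.00089, adjusted p = 0.544 with an estimated correlation). The 33 type I interferon response genes had a median of 0.04 (0 rose, 0 fell, also adjusted over the list alone, camera adjusted p = 0.65).

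**Figure D2:**
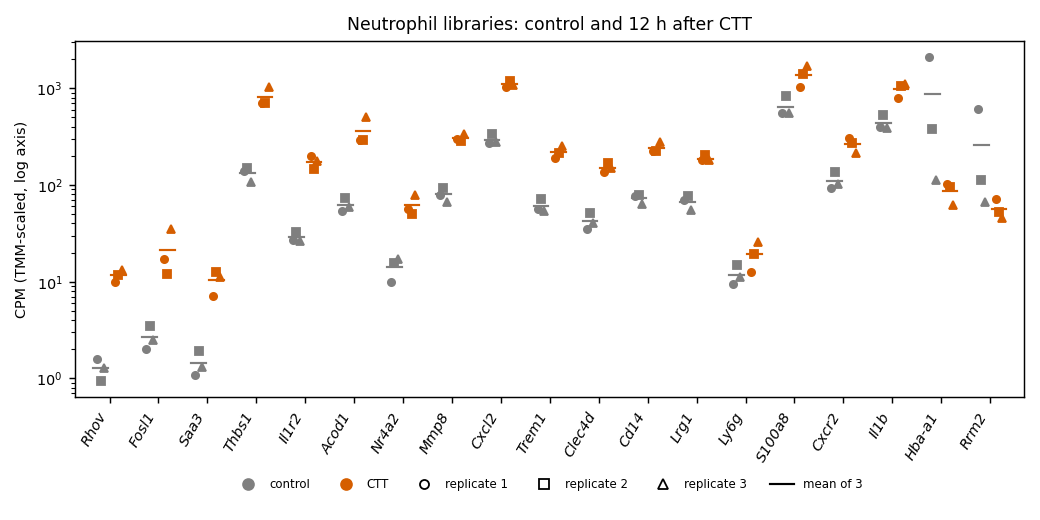
CPM (TMM-scaled, log axis) of 19 named genes in each control (grey) and CTT (orange) neutrophil library, with the replicate number as the marker shape and a line at the mean of 3. Thbs1, Il1r2 and Cxcl2 are higher in each CTT library than in any control, and Hba-a1 and Rrm2 are highest in control replicate 1, at 2103 and 603 CPM.

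Among the 11 neutrophil genes fixed before the data were examined, 0 rose and 0 fell over all genes in the edgeR quasi-likelihood test, and 7 rose adjusted over the list alone. Cxcr2, the chemokine receptor that draws neutrophils from marrow to tissue, had a log2 fold change of 1.25 (SE 0.20, adjusted p = 0.058), Il1b, interleukin-1 beta, 1.17 (SE 0.19, adjusted p = 0.0636) and Cxcr4, the marrow retention receptor, 0.86 (SE 0.21, adjusted p = 0.174). All 3 rose without control replicate 1, with adjusted p-values of 0.0185, 0.0249 and 0.0418. The calprotectin subunit genes S100a8 (1.09, SE 0.24, adjusted p = 0.128) and S100a9 (1.05, SE 0.28, adjusted p = 0.211) did not pass, nor did Ly6g (0.70, SE 0.29, adjusted p = 0.351), Cd274, which encodes PD-L1 (0.88, SE 0.32, adjusted p = 0.338), or Tnf (1.09, SE 0.56, adjusted p = 0.395). Arg1, arginase 1, read 1.14 ± 0.250 CPM in control and 7.96 ± 7.18 CPM after CTT (2.80, SE 0.65, adjusted p = 0.156). Nos2, inducible nitric oxide synthase, read 0.339 ± 0.385 and 0.739 ± 0.369 CPM (1.11, SE 0.93, adjusted p = 0.565), and the adhesion molecule gene Icam1 had a log2 fold change of 0.21 (SE 0.16, adjusted p = 0.512).

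In all, 74 of 13058 tested genes rose and 0 fell after CTT, 65 of them with a log2 fold change above 1, and 1830 genes had an unadjusted p below 0.05 in the edgeR test. DESeq2 gave 107 genes that fell, limma-voom 0 and limma-trend on FPKM 1, and DESeq2 gave 455 that rose. The 3 control and 3 CTT values did not overlap in 3220 genes (24.7%, where chance gives 10%), among them all 74 that rose. Leaving out control replicate 2 or 3, or CTT replicate 1, 2 or 3, left 0 genes past the threshold in edgeR. In these fits 1848, 2662, 1311, 1023 and 944 genes had an unadjusted edgeR p below 0.05. Each of the 74 calls was thus lost in each of these 5 fits. All 5 had fewer libraries and kept control replicate 1, so the loss cannot be assigned to the values of the library left out. Without control replicate 1, 257 genes rose, including all 74, and 31 fell. With all 6 libraries and the replicate number as a block, 4 genes rose and 1 fell.

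In monocytes selected 5 days after CTT, anti-Ly6G treatment went with higher neutrophil-type and inflammatory monocyte transcripts and with lower levels of some heat shock, macrophage and MHC class II transcripts. Prok2, a secreted attractant peptide of myeloid cells, went from 0.842 ± 0.0530 CPM (SD, n = 3) with CTT alone to 31.7 ± 7.06 CPM (n = 3) with the antibody, a log2 fold change of 5.23 (SE 0.22). Lipg, endothelial lipase, rose by 4.22 (SE 0.31), Ggt1, a glutathione-cleaving enzyme, by 3.91 (SE 0.35), Saa3 by 3.13 (SE 0.24), the adhesion molecule gene Mcam by 2.60 (SE 0.15), Vcan, the proteoglycan versican, by 2.48 (SE 0.26) and Upp1, uridine phosphorylase, by 2.37 (SE 0.14). Hspa1b and Hspa1a, the inducible HSP70 chaperones, fell by 2.67 (SE 0.25) and 2.63 (SE 0.24) on the log2 scale, Hspa1b from 1391 ± 283 to 219 ± 80.6 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p-values of these 9 genes lay between 2.94e-05 (Prok2) and 0.000636 (Vcan), with no overlap between the groups.

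The genes with the next largest falls were Col14a1, a fibril-associated collagen (log2 fold change −1.57, SE 0.24), Ptgs2, cyclooxygenase-2 (−1.32, SE 0.28), Hpn, the serine protease hepsin (−1.27, SE 0.18), Sned1 (−1.18, SE 0.21) and Tpbgl (−1.18, SE 0.28), with edgeR adjusted p-values from 0.00245 (Hpn) to 0.0258 (Tpbgl). Ptgs2 and Tpbgl lost their calls in edgeR when single libraries were left out, with adjusted p of up to 0.0534 without anti-Ly6G replicate 3 for Ptgs2 and 0.0996 without anti-Ly6G replicate 1 for Tpbgl. All are annotated as protein coding on GRCm38 (mm10). Prok2 (Entrez gene 50501) lies on chromosome 6 from 99711299 to 99726392, Lipg (16891) on chromosome 18 from 74939322 to 74961263 and Col14a1 (12818) on chromosome 15 from 55307644 to 55520803. Hspa1b (15511) lies on chromosome 17 from 34956429 to 34959238 and its near copy Hspa1a (193740) from 34969359 to 34972156, so reads may be split between them and their separate values are uncertain.

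Neutrophil transcripts were higher with the antibody against the neutrophil marker. Of 17 neutrophil markers 16 rose and 0 fell, with the same counts adjusted over the list alone, and their summed level was 5426 ± 968 CPM with CTT alone and 15814 ± 2369 CPM with anti-Ly6G. Ly6g itself rose by a log2 fold change of 2.04 (SE 0.14, edgeR adjusted p = 0.000106), S100a8 by 1.78 (SE 0.14) and S100a9 by 1.65 (SE 0.13). For this list the median was 1.74, with a camera adjusted p = 9.7e-17, and adjusted p = 0.237 with an estimated correlation. All 17 genes of the secondary and tertiary granule list rose, also adjusted over the list alone. They included Mmp8 (2.22, SE 0.14), Padi4, which citrullinates histones (1.34, SE 0.08), and the haptoglobin gene Hp (1.55, SE 0.12). This list shares 4 of its genes with the classical monocyte list. The list had a median of 1.51 (camera adjusted p = 2.11e-16, adjusted p = 0.364 with an estimated correlation). Of 9 primary granule genes 5 rose, with 7 adjusted over the list alone, including the serine proteases Ctsg (2.00, SE 0.43) and Prtn3 (1.99, SE 0.44) and Cebpe, a transcription factor of granulocyte maturation (1.54, SE 0.27); Ctsg and Prtn3 lost the call without CTT replicate 3 (edgeR adjusted p = 0.0752 and 0.0765). The median over the list was 1.52 (camera adjusted p = 2e-04, adjusted p = 0.534 with an estimated correlation). Of 17 mature neutrophil receptor genes 12 rose, with 13 rising and 1 falling adjusted over the list alone, led by Retnlg (1.89, SE 0.09). Over the list the median was 0.74 (camera adjusted p = 6.5e-10, adjusted p = 0.237 with an estimated correlation).

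Genes of classical monocytes rose as well. Of 17 such genes 14 rose and 1 fell, also adjusted over the list alone. The group had a median of 1.05 (camera adjusted p = 1.75e-09, adjusted p = 0.364 with an estimated correlation). Ccr2, the target of the selection, went from 216 ± 41.5 to 513 ± 73.9 CPM (log2 fold change 1.25, SE 0.14), Ly6c2, the Ly6C surface marker, rose by 1.24 (SE 0.20), Plac8 by 0.68 (SE 0.07) and Cd177, a surface glycoprotein that neutrophils also carry, by 1.99 (SE 0.22). Csf1r was the member that fell (−0.56, SE 0.15, edgeR adjusted p = 0.0363, with 4 libraries whose removal ended the call and an adjusted p of up to 0.105, without anti-Ly6G replicate 3). Of 17 nonclassical monocyte genes 7 rose and 4 fell, with 7 and 5 adjusted over the list alone, and those that rose included the peptidase gene Ace (0.52, SE 0.06) and the surface sialoglycoprotein gene Spn (0.63, SE 0.08). The group's median was 0.15 (camera adjusted p = 0.169). The 13 monocyte markers were mixed, with 7 that rose and 4 that fell, also adjusted over the list alone. Their median was 0.52 (camera adjusted p = 0.0264, adjusted p = 0.633 with an estimated correlation, and 0.0829 in camera without CTT replicate 2). They summed to 5726 ± 1340 CPM with CTT alone and 6052 ± 412 CPM with anti-Ly6G. Neutrophil markers rose in the same libraries, and their own summed levels are given above.

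Glycolysis, cell cycle, type I interferon and acute phase genes rose in part with the antibody. Of 26 glycolysis and hypoxia genes 19 rose and 1 fell, with 20 and 1 adjusted over the list alone, among them the lactate exporter gene Slc16a3 (1.14, SE 0.09) and the enzymes Pkm (0.79, SE 0.07), Eno1 (0.64, SE 0.06) and Pgk1 (0.70, SE 0.08). The list's median was 0.47 (camera adjusted p = 8.91e-12, adjusted p = 0.237 with an estimated correlation). The member that fell, named after its value was seen, was Pdk1, a kinase that inhibits pyruvate dehydrogenase (−0.31, SE 0.08, edgeR adjusted p of up to 0.0973 without anti-Ly6G replicate 1). Of 30 cell cycle genes 19 rose and 0 fell, with 23 adjusted over the list alone, among them cyclin A2, Ccna2 (0.60, SE 0.08), the spindle factor Tpx2 (0.50, SE 0.07) and cyclin B1, Ccnb1 (0.67, SE 0.10). The list had a median of 0.41 (camera adjusted p = 1.02e-11, adjusted p = 0.53 with an estimated correlation). Of 33 type I interferon response genes 18 rose and 0 fell, with 21 adjusted over the list alone, led by the antiviral synthetases Oas3 (1.38, SE 0.13) and Oas2 (1.04, SE 0.12). The median over the list was 0.44 (camera adjusted p = 2.76e-09, adjusted p = 0.534 with an estimated correlation). Of 19 interferon gamma GTPases and targets 2 rose and 0 fell, also adjusted over the list alone. They were the GTPases Irgm1 (0.35, SE 0.09) and Ifi47 (0.33, SE 0.08), with edgeR adjusted p-values of up to 0.107 and 0.099 without CTT replicate 3 and above the threshold also without CTT replicate 2 or anti-Ly6G replicate 2 or 3. This list's median and mean lay just under 0, at −0.01 and −0.003, while its camera test pointed up (camera adjusted p = 0.993). Of 17 acute phase and STAT3 target genes 11 rose, with 12 rising and 1 falling adjusted over the list alone, with Lrg1 at 1.82 (SE 0.09) and Ifitm1, a membrane protein that restricts virus entry, at 1.47 (SE 0.11). Over the list the median was 0.62 (camera adjusted p = 5.57e-09, adjusted p = 0.237 with an estimated correlation). Neutrophil markers were higher in the same libraries, at 15814 ± 2369 against 5426 ± 968 CPM.

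Heat shock, immediate early, macrophage, MHC class II and costimulation genes fell in part with the antibody. Of 15 heat shock genes 7 fell and 0 rose, also adjusted over the list alone, with the chaperones Hsph1 (−1.12, SE 0.09) and Dnajb1 (−1.02, SE 0.11) beside Hspa1a and Hspa1b. The group had a median of −0.23 (camera adjusted p = 2.28e-05, adjusted p = 0.398 with an estimated correlation). Of 20 immediate early genes 8 fell, with 10 adjusted over the list alone, among them Klf6 (−0.38, SE 0.05) and the AP-1 gene Fosb (−0.69, SE 0.13). The group's median was −0.25 (camera adjusted p = 0.000158, adjusted p = 0.292 with an estimated correlation). Of 13 red pulp macrophage markers 9 fell, with 10 falling and 1 rising adjusted over the list alone. For this list the median was −0.71 (camera adjusted p = 3.36e-05, adjusted p = 0.542 with an estimated correlation). They included Adgre1, which encodes F4/80 (−0.71, SE 0.13), the hemoglobin scavenger receptor Cd163 (−0.98, SE 0.18), the receptor for dying cells Axl (−0.87, SE 0.19) and the adhesion molecule Vcam1 (−0.78, SE 0.18), the last 2 losing the call without anti-Ly6G replicate 3 (edgeR adjusted p = 0.0641 and 0.0809). The summed macrophage markers stood at 16792, 10120 and 11606 CPM in the 3 CTT libraries and at 8003 to 8762 CPM with anti-Ly6G.

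Of 13 MHC class II presentation genes 7 fell and 1 rose, with 10 and 1 adjusted over the list alone. The list had a median of −0.33 (camera adjusted p = 2e-04, adjusted p = 0.53 with an estimated correlation). Cd74 went from 7071 ± 406 to 5404 ± 424 CPM (−0.39, SE 0.07) and H2-Ab1 had a log2 fold change of −0.32 (SE 0.08), while Ifi30, a lysosomal thiol reductase, rose by 0.40 (SE 0.07); without anti-Ly6G replicate 1 the edgeR adjusted p of Cd74 was 0.0516 and that of H2-Ab1 0.104. Of 19 MHC class I presentation genes 1 rose and 0 fell, with 0 and 0 adjusted over the list alone, and their median was 0.05 (camera adjusted p = 0.846). The gene that rose was the immunoproteasome subunit Psmb10 (0.22, SE 0.06). It was past the threshold with all 6 libraries and without CTT replicate 1, and not with any other library left out (highest edgeR adjusted p = 0.115 without anti-Ly6G replicate 1) nor with upper-quartile normalization, library totals or all 12 libraries in 1 fit. Of 11 costimulation genes 3 fell and 1 rose, with 7 and 1 adjusted over the list alone, the falls being Cd83 (−0.61, SE 0.10), Cd80 (−0.48, SE 0.10) and Cd86 (−0.56, SE 0.11), ligands and a marker of antigen presenting cells, and the rise, named after its value was seen, being the cytokine gene Tnfsf14 (0.36, SE 0.10, past the threshold only with all 6 libraries, with an edgeR adjusted p of up to 0.126 without anti-Ly6G replicate 2); without anti-Ly6G replicate 1, Cd80 and Cd86 had edgeR adjusted p-values of 0.0549 and 0.0552. The median over the list was −0.29 (camera adjusted p = 0.00278, adjusted p = 0.237 with an estimated correlation). Of 19 M2-type macrophage genes 6 fell and 2 rose, with 7 and 2 adjusted over the list alone, with the mannose receptor Mrc1 at −0.98 (SE 0.19) and Chil3, a chitinase-like protein that neutrophils also make, at 1.34 (SE 0.26). Over the list the median was −0.35 (camera adjusted p = 0.0221, adjusted p = 0.542 with an estimated correlation, and a camera adjusted p = 0.0802 without CTT replicate 1). Cd163 belongs to both this list and the red pulp macrophage markers. Of 19 M1-type macrophage genes 2 rose and 3 fell, with 3 and 3 adjusted over the list alone. Their median was −0.141 and their mean 0.175, and camera did not call the list (camera adjusted p = 0.444). Of 12 B cell markers 2 fell, with 10 adjusted over the list alone. Among them was Fcer2a (−0.62, SE 0.16), which lost the call with single libraries left out (highest edgeR adjusted p = 0.128 without anti-Ly6G replicate 1). The group had a median of −0.47 (camera adjusted p = 4.54e-05, adjusted p = 0.542 with an estimated correlation).

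**Figure D3:**
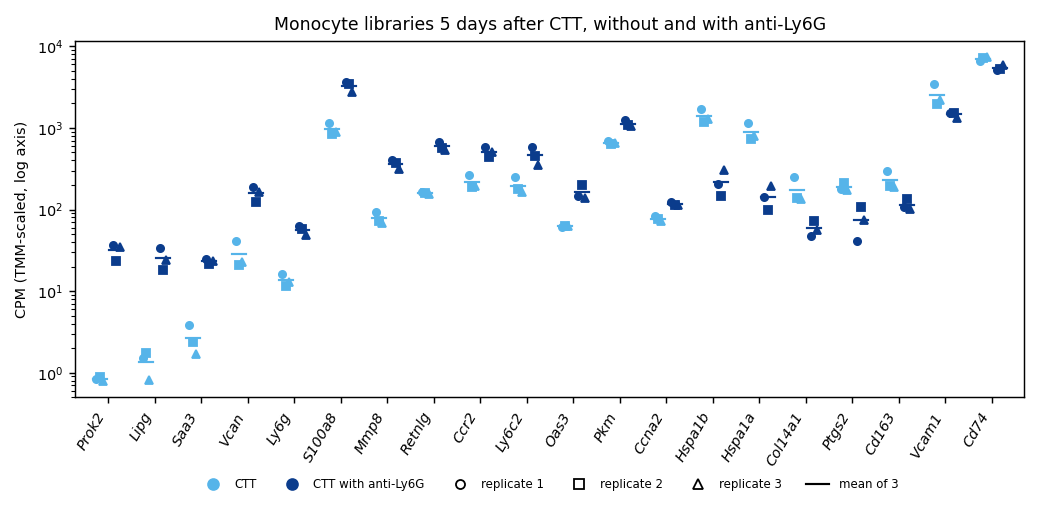
CPM (TMM-scaled, log axis) of 20 named genes in each monocyte library 5 days after CTT, without (light blue) and with (dark blue) anti-Ly6G, with the replicate number as the marker shape and a line at the mean of 3. Ly6g, S100a8 and Prok2 are higher in all 3 anti-Ly6G libraries, and Hspa1a, Hspa1b and Cd163 are lower.

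Among the 12 monocyte genes fixed before the data were examined, 7 rose, 2 fell and 3 did not pass, with 7 and 3 adjusted over the list alone. Ccr2, Ly6c2, Ly6g, S100a8 and S100a9 rose as given above, as did Cx3cr1, the fractalkine receptor of nonclassical monocytes (log2 fold change 0.61, SE 0.07, edgeR adjusted p = 0.000905). Nos2 rose from 0.103 ± 0.0653 to 3.84 ± 1.03 CPM (5.19, SE 0.48, adjusted p = 0.000381). Arg1 fell (−1.28, SE 0.31, edgeR adjusted p = 0.0272, and 0.104 without anti-Ly6G replicate 1), and so did Cd86. H2-Aa (−0.30, SE 0.09, adjusted p = 0.0524), Tnf (−0.08, SE 0.11, adjusted p = 0.687) and Il12b, a subunit of interleukin-12 (−0.53, SE 0.55, adjusted p = 0.556), did not pass. Fisher's exact test on annotated terms gave 84 of 345 innate immune response genes that rose (adjusted p = 2.44e-10, led by Wfdc17, Padi4 and Tarm1), 32 of 78 genes of the defense response to bacterium (3.69e-09, led by Pglyrp1, Hp and Clec4e) and 14 of 27 of the glycolytic process (5.59e-05, led by Pkm, Eno1 and Pgk1). For comparison, 1354 of all 13294 tested genes rose. Padi4 and Hp belong to the granule list and Clec4e to the mature neutrophil receptor list. The innate immune and bacterial defense terms therefore do not tell monocyte from neutrophil transcripts. Among the terms of genes that fell was chaperone cofactor-dependent protein refolding, with 11 of 32 genes (adjusted p = 0.0012, led by Hsph1, Hspa1a and Hspa1b).

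In all, 1354 of 13294 tested genes rose and 681 fell with anti-Ly6G, of which 259 and 62 had an absolute log2 fold change above 1. With upper-quartile normalization 1069 rose and 1030 fell. The values of the groups did not overlap in 4784 genes (36%, where chance gives 10%), among them 2030 of the 2035 called genes. Leaving out any single library moved the count of genes that rose, the count that fell or both by more than 1.5 times. They became 1687 and 1168 without CTT replicate 1, 875 and 531 without CTT replicate 2, 706 and 278 without CTT replicate 3, and 761 and 177, 870 and 318, and 929 and 281 without anti-Ly6G replicate 1, 2 and 3.

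The genes that rose in the 2 comparisons, which share no libraries, overlapped. Of 12793 genes tested in both, 73 rose in neutrophils after CTT and 1344 in monocytes with anti-Ly6G, and 52 rose in both, where independent lists would share 7.67. Neutrophil markers were higher in both comparisons, with list medians of 1.07 and 1.74. The overlap therefore cannot tell a shared response from a larger share of neutrophil cells in each. The shared genes included Il1r2, Saa3, Mmp8, Trem1, Cxcl2, Lrg1 and Osm, whose log2 fold changes in monocytes were lower for Il1r2 (0.74 against 2.60) and higher for Lrg1 (1.82 against 1.49), differences that were not tested. Another 2 genes, named after their values were seen, rose in neutrophils and fell in monocytes, against 3.85 for independent lists, the chaperone gene Dnajb4 (1.25, SE 0.18, and −0.62, SE 0.10) and Hcar2, a receptor for hydroxybutyrate (1.40, SE 0.20, and −0.65, SE 0.15, the fall with an edgeR adjusted p of up to 0.083 without anti-Ly6G replicate 1). Across all genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at a Pearson r of 0.107 and a Spearman correlation of −0.041. Without control replicate 1 of the neutrophils, 135 genes rose in both, against 26.8 for independent lists. Without neutrophil control replicate 2 or 3, or CTT replicate 1, 2 or 3, 0 genes rose in neutrophils in edgeR and the overlap was 0. With single monocyte libraries left out it was 44 to 54 genes.

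**Figure D4:**
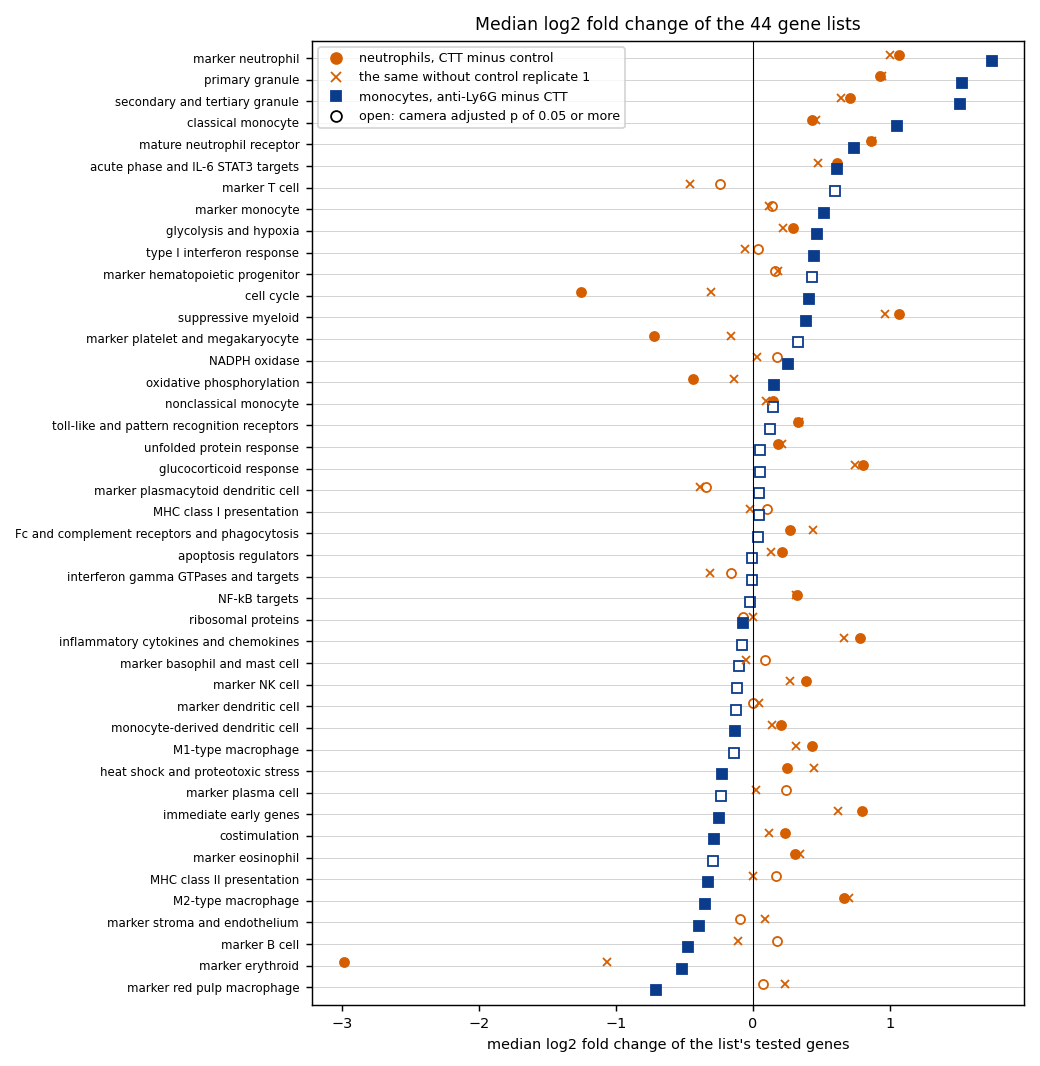
Median log2 fold change of the tested genes of each of the 44 gene lists in neutrophils after CTT (orange circles, with crosses for the fit without control replicate 1) and in monocytes with anti-Ly6G (blue squares); open symbols have a camera adjusted p of 0.05 or more. Neutrophil markers are at 1.07 and 1.74, and the erythroid markers at −2.98 in neutrophils move to −1.07 without control replicate 1.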

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

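Library quality weights, robust estimation and the overlap with 1 library left out were chosen after seeing the data, and the cause of each change below was not tested unless stated. In neutrophils, the 74 genes that rose and 0 that fell became 455 and 107 with DESeq2, 49 and 1 with FPKM plus 1, and 56 and 1 with FPKM plus 0.1. They became 8 and 0 with unfiltered FPKM and 713 and 163 with quality weights. All 12 libraries in 1 fit, where both cell types share 1 dispersion per gene, gave 535 that rose and 102 that fell. With 1 library left out, which leaves fewer samples, 0 to 257 rose and 0 to 31 fell. Normalization, filters, limma-voom, robust estimation and gene type gave 53 to 80 that rose and 0 that fell. In monocytes, 1354 and 681 became 1069 and 1030 with upper-quartile normalization, 1566 and 1204 with DESeq2, 883 and 322 with unfiltered FPKM, 410 and 90 with all 12 libraries in 1 fit, 1824 and 1160 with quality weights, and, by construction, 259 and 62 with a minimum absolute log2 fold change of 1. With 1 library left out, 706 to 1687 rose and 177 to 1168 fell. The 52 genes that rose in both became 22 with the minimum log2 fold change, 50 with DESeq2 size factors, 135 without neutrophil control replicate 1, 0 without any other neutrophil library, where 0 rose in neutrophils, and 44 to 54 with 1 monocyte library left out. With the replicate number as a block, 4 genes rose and 1 fell in neutrophils, and 1551 rose and 1043 fell in monocytes. The labels pair nothing by number, so the block is used only as an alternative setting. The deviations of same-numbered libraries correlated at 0.199, 0.005 and 0.189 in neutrophils and 0.065, −0.027 and 0.087 in monocytes. Replicates 1 and 3 of both cell types correlated best with their own number. Replicate 2 did not (control 2 at 0.156 with CTT 3, and CTT 2 of the monocytes at 0.034 with anti-Ly6G 3). A pairing by number can therefore be neither shown nor set aside.

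Of the 44 lists, camera called 24 up and 4 down in neutrophils and 13 up and 11 down in monocytes. With an estimated correlation 0 were up and 0 down in both. With fry 4 were up and 0 down in neutrophils, and 10 up and 3 down in monocytes. The block gave 26 up and 4 down, and 13 up and 12 down. With 1 library left out, 18 to 29 were up and 3 to 7 down in neutrophils, and 12 to 14 up and 9 to 12 down in monocytes. Of 48 genes named in neutrophils, 29 past the threshold, single results kept direction and side of the threshold in 659 cases over the settings that keep all libraries, newly passed in 29 and no longer passed in 68. For 91 genes named in monocytes, 87 past the threshold, these numbers were 1390, 9 and 51. With 1 library left out they were 134, 5 and 145 in neutrophils and 485, 2 and 59 in monocytes. The only named gene that changed sign was Csf1r in neutrophils, whose log2 fold change of 0.01 was small throughout, at 0 with DESeq2 and its size factors, −0.0517 with library totals, −0.0163 with limma-voom, −0.0736 with FPKM plus 1 (filtered or not), −0.0741 with FPKM plus 0.1, −0.0148 with the replicate block and −0.0933 to 0.195 with 1 library left out. Depth was alike in all libraries and limits only genes of a few CPM.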

Other observations

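Further gene groups were tested between the monocyte libraries with and without anti-Ly6G, of which the NADPH oxidase, suppressive myeloid and stromal lists passed camera with its preset correlation and the others given here did not. Of 9 NADPH oxidase genes 6 rose and 1 fell, also adjusted over the list alone, among them cytosolic subunits of the enzyme that makes superoxide, Ncf1 (0.64, SE 0.06) and Ncf4 (0.62, SE 0.08). The group's median was 0.25 (camera adjusted p = 0.000374, adjusted p = 0.292 with an estimated correlation). Of 23 suppressive myeloid genes 9 rose and 2 fell, with 12 and 4 adjusted over the list alone, with Wfdc17, a small secreted protein, at 1.53 (SE 0.09). The list's median was 0.38 (camera adjusted p = 0.00587, adjusted p = 0.534 with an estimated correlation). Of 25 toll-like and pattern recognition receptor genes 9 rose and 2 fell, with 10 and 3 adjusted over the list alone, including the adaptor Myd88 (0.63, SE 0.05). The list had a median of 0.13 (camera adjusted p = 0.131). Of 20 genes for Fc and complement receptors and phagocytosis 4 rose and 4 fell, also adjusted over the list alone, with the integrin gene Itgam, which encodes CD11b, at 1.01 (SE 0.11) and Timd4, a macrophage receptor for dying cells, at −0.82 (SE 0.14). The median over the list was 0.03 (camera adjusted p = 0.781). Of 25 inflammatory cytokine and chemokine genes 4 rose and 0 fell, with 7 and 3 adjusted over the list alone, and the list's median (−0.08) and mean (0.11) differed in sign (camera adjusted p = 0.593); Osm rose by 0.83 (SE 0.07) and Cxcl2 by 0.90 (SE 0.11). Of 21 NF-kB target genes 2 rose and 3 fell, with 2 and 4 adjusted over the list alone, with Bcl3 at 0.62 (SE 0.08), the inhibitor Nfkbid at −0.64 (SE 0.07) and the deubiquitinase Tnfaip3 at −0.51 (SE 0.10). Over the list the median was −0.02 (camera adjusted p = 0.444). Of 11 stromal and endothelial markers 3 fell and 1 rose, with 5 and 1 adjusted over the list alone, with the adhesion molecule Pecam1 at −0.57 (SE 0.07) and Kdr, a receptor for VEGF, at 0.91 (SE 0.16). The group had a median of −0.40 (camera adjusted p = 0.0306, adjusted p = 0.572 with an estimated correlation, and 0.0824 in camera without CTT replicate 1). The summed neutrophil markers in these libraries were 15814 ± 2369 CPM with the antibody and 5426 ± 968 CPM without.

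In neutrophils after CTT, 1 of 15 glucocorticoid response genes rose, Il1r2 (2.60, SE 0.17), and 10 did when adjusted over the list alone, with 4 past the test and a median of 0.74 without control replicate 1. The group's median was 0.80 (camera adjusted p = 1.39e-07, adjusted p = 0.273 with an estimated correlation). The clock gene Per1, induced by glucocorticoids, had a log2 fold change of 1.22 (SE 0.20, edgeR adjusted p = 0.0752). Of 17 classical monocyte genes 2 rose, Cd14 (1.72, SE 0.15) and Vcan (1.78, SE 0.26), with 5 adjusted over the list alone, and 3 rose without control replicate 1. The list's median was 0.43 (camera adjusted p = 2.28e-06, adjusted p = 0.477 with an estimated correlation). None of 21 NF-kB target genes (0 of 21 in edgeR, 7 adjusted over the list alone, median 0.32, camera adjusted p = 1.18e-05, adjusted p = 0.477 with an estimated correlation, 2 without control replicate 1) and none of 26 glycolysis and hypoxia genes (0 of 26, 3 adjusted over the list alone, median 0.29, camera adjusted p = 0.013, adjusted p = 0.477 with an estimated correlation, and 0.0909 in camera without CTT replicate 3, 3 without control replicate 1) passed over all genes. Hdc, the enzyme that makes histamine, rose by 1.42 (SE 0.14) as the only one of 8 basophil and mast cell markers. The 12 B cell markers had a median of 0.18 (0 rose, 0 fell in edgeR, also adjusted over the list alone, camera adjusted p = 0.134, and adjusted p = 0.759 with an estimated correlation). Without control replicate 1 their median was −0.11, 1 fell and camera called the list down (camera adjusted p = 0.00728).

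Of the tests that follow, the one on gene length and the splits of the libraries were set before their results were seen, and the others were chosen after. Control replicate 1 of the neutrophils stood apart from the other 5 libraries. All 16 of 16 erythroid markers were at least 2 times as high in it as in each other control library, with Hbb-bs, a beta globin gene, at 3723 CPM against 657 and 220 CPM, so that erythroid cells in this library are a candidate source of part of the difference, as a hypothesis formed on the same data; none of these markers belongs to another list, and the selection on Ly6G would be meant to remove such cells. A gene length bias was weighed through the correlation across genes of gene length with the log2 CPM of this library minus the mean of the other controls, which gave a Spearman correlation of −0.174, between the bounds set for and against it, so that a contribution of length cannot be told apart from that of the genes' own levels. The design gives this library no group of its own, and no biological explanation was tested.

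In the neutrophil libraries after CTT, 5 of 17 receptor genes, 3 of 26 inflammatory cytokine genes and 2 of the 16 neutrophil markers used for comparison rose (medians 0.86, 0.78 and 1.07, camera calls lost at an adjusted p = 0.273, 0.477 and 0.443 with an estimated correlation); control replicate 1 alone is argued against, since the median of the mature receptor list was 0.87 with that library left out and 0.86 with it. A larger share of neutrophils among the selected cells and a change within the neutrophils cannot be told apart for the receptor and the inflammatory cytokine lists. Their mean log2 CPM per library minus that of the markers, without shared genes, changed after CTT by −0.042 (SE between libraries 0.166) and −0.248 (SE 0.157), which is too wide to show that they moved alike, and either explanation can raise markers and lists together. The abundant neutrophil genes Ngp, S100a9 and S100a8 stood at 2291, 2009 and 1371 CPM after CTT, and 6 of the 18 listed markers also belong to the granule list and 3 to the receptor list. A response of neutrophils to CTT, which the design names, stays open, and the selection on Ly6G was the same in both groups.

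Neutrophil transcripts were higher and macrophage transcripts lower in the monocyte libraries with anti-Ly6G. A lower share of red pulp macrophages that raises all other cell types alike is argued against, since B cell markers did not rise. They summed to 4147 to 6090 CPM with CTT alone and 3232 to 4447.5 CPM with anti-Ly6G. Neutrophil markers summed to 4790 to 6540 and 13163 to 17724 CPM. The list medians differed by 2.215. The SD of 0.84 among the neutrophil markers is a spread between genes, not between libraries. The rise of the neutrophil markers was known before this comparison was chosen, and only an equal rise of all other cell types is addressed. Neutrophil-lineage cells among the cells selected on CCR2 are a candidate source, as a hypothesis formed on the same data. In these libraries 16 of 17 neutrophil markers rose, with a median of 1.70 over the 16 markers in no monocyte list. S100a9 and S100a8 stood at 4718 and 3286 CPM with anti-Ly6G. These values are part of the pattern itself and do not test its source. A change within the monocytes themselves cannot be told apart from neutrophil-lineage cells. The 12 classical monocyte genes in no neutrophil list had a median of 0.757 (9 rose, 1 fell), so both kinds of transcript rose together. The effect of the antibody on monocytes, which the design names, stays open for these genes.

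Of the 10 splits of the 6 neutrophil libraries into 3 and 3, 1 gave as many genes as the real one, which was itself (74 genes, highest of the other splits 0), and the same held for the monocyte libraries, with 1 of 10 (2035 genes, highest of the other splits 0). With 10 splits, a share under 0.05 cannot be reached.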
